A study of Mus musculus with 4 samples.

How the data were processed

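RNA sequencing was carried out on bone marrow cells selected with CD117 (KIT) microbeads, a surface marker of hematopoietic stem and progenitor cells (HSPCs), from wild-type mice and from mice with an inducible form of HIF-1α. Per the labels, each genotype has 2 libraries and the strain background is C57BL/6, 129X1/SvJ. Nothing in the labels says whether the libraries of one genotype came from separate mice, so p-values measure the spread between these libraries, which may be technical. Age, time after induction and the species of the induced HIF-1α sequence are not given in the sources used here.

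The deposited table holds raw counts per gene for 24415 Entrez gene identifiers, one column per library. Per the submitters' processing notes, the tools named were bcl2fastq, CASAVA 1.8, TopHat and edgeR, and the genome build was mm10. The counting tool, its annotation, its treatment of multi-mapped reads and its strand setting are not given in the sources used here. Identifiers were matched to symbols and coordinates in a RefSeq gene table of GRCm38.p6, the assembly behind mm10. The 81 identifiers without a match held between 0.911% and 1.45% of each library's counts and were kept in the tests under their identifiers. The deposited counts include 110 rows, in 47 groups, whose values in all 4 libraries are identical to those of another row (among rows with at least 40 counts in sum). These rows, such as Hba-a1 and Hba-a2, held 1.59% to 2.55% of the counts, so some reads were counted for more than 1 gene. Genes with near-identical copies, among them the globins, ribosomal proteins and MHC genes, have counts that cannot be assigned to a single copy with certainty. Because the strand setting is not given, it is not known whether reads of a gene and an overlapping antisense gene were separated.

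Total counts were 27539149 and 22221798 in the wild-type libraries and 24852965 and 26373177 in the inducible HIF-1α libraries. At these depths 3 counts, the limit that a count of 0 allows, corresponded to between 0.112 and 0.139 CPM (the count scaled to library size) per library. That limit and the intervals given for ratios of summed counts (exact, 95%) cover counting error only. Replicates were compared before they were averaged. The wild-type pair differed by a chi-square of 23.3 per degree of freedom over 13883 genes and the inducible HIF-1α pair by 119 over 13611 genes, so no library was a copy of another.

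Differential expression was tested in R 4.3.3 with edgeR 4.0.16, which the submitters' notes also name. Genes were kept by filterByExpr with its default minimum count of 10, which left 14043 genes, and libraries were scaled by TMM. A quasi-likelihood F test (glmQLFit, glmQLFTest) compared the genotypes across all 4 libraries without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by the TMM library sizes. Errors of CPM are SDs over 2 libraries and the standard error (SE) of a log2 fold change is its size divided by the square root of F. Fold changes of genes with 0 to 3 counts over a whole group are given as a bound against 3 counts over the group, or as a ratio of summed counts with its interval. Adjusted p-values of single genes below come from this test.

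Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 28 tested lists cover HIF-1 target genes, HIF pathway components, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation subunits, stem cell, erythroid, megakaryocyte, neutrophil, monocyte and macrophage, dendritic, mast, eosinophil, B, T and NK, and stromal markers, heme synthesis, iron handling, interferon, TNF and NF-kB, fibrosis-linked, replication, p53, MDS driver, stress, immediate early and ribosomal protein genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move on balance one way. Ahsp, Ly6g and Ighm, members of these lists, were not analysed here.

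The genes named are Hif1a, the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 1, no overlap between the groups and an established symbol, and for each list up to 4 called members with the smallest p or, where none was called, the 1 member with the smallest p. Not every gene that the rule took is given in the text. Members named because they passed only when adjusted over the list alone were chosen after their values were seen, as were the others marked so.

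Alternatives were other scalings (size factors of the DESeq2 type, upper quartile, total count), other tools (DESeq2 1.42.0, edgeR's exact test, limma-voom), other filters (none, or at least 1 CPM in all 4 libraries), leaving out the 10 most abundant genes, other thresholds, a replicate block, leaving out each library, and counting identical rows as 1, the last chosen after seeing the data. The fits were tested on simulated data drawn from the means and dispersions of this comparison. Each gene was drawn independently, with the same dispersion in both genotypes. Of 13749 genes tested there, 18.5% of those changed by a log2 value of 1, 73.8% of those changed by 2 and 87.9% of those changed by 3 were called in the right direction, and 5 of 13523 unchanged genes were called. A simulated list of 30 genes shifted by 0.6 was called by camera at the preset correlation and by fry (adjusted p = 0.0141) but not with an estimated correlation (adjusted p = 0.0625).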

Results

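Transcript levels were measured by RNA sequencing in CD117-selected bone marrow cells from wild-type mice and from mice carrying an inducible, constitutively active HIF-1α, the oxygen-regulated subunit of the hypoxia-inducible transcription factor HIF-1. Each genotype was represented by 2 libraries with 22221798 to 27539149 counts. The single comparison was inducible HIF-1α against wild type. It addresses which transcripts differ in CD117-selected cells of a model that the series title links to myelodysplastic syndrome (MDS). Markers of mature cells were also detected, so a difference cannot be assigned to HSPCs alone. The inducible HIF-1α libraries differed more from each other (biological coefficient of variation 33.3%) than the wild-type libraries did (15%).

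Hif1a itself (Entrez 15251; chromosome 12, 73901324 to 73947554 in GRCm38) was not higher in the inducible HIF-1α libraries. Its level was 173.7 ± 7.5 CPM in wild type and 133.9 ± 30 CPM in inducible HIF-1α (SD, n = 2 each), a log2 fold change of -0.38 ± 0.21 (SE; adjusted p = 0.426). The counts belong to the mouse gene, and whether they include the induced transcript is not given in the sources used here. Without inducible HIF-1α replicate 1 the log2 fold change was -0.63 (adjusted p = 0.00376), and without inducible HIF-1α replicate 2 it was -0.13 (adjusted p = 0.758). The adjusted p reached 0.985 without wild-type replicate 2, the highest of the 9 alternatives run for this gene.

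Among 14043 genes tested, 16 were higher and 141 were lower in the inducible HIF-1α libraries. Of these, 118 genes fell and 11 rose by more than 2 on the log2 scale. The 8 largest rises were in Podxl, Redrum, Erfe, Cttnbp2, Clca3a1, Cish, Fabp5 and Fads3. Podxl, which encodes the sialomucin podocalyxin (chromosome 6, 31519493 to 31563937), rose from 1.17 ± 0.147 to 98.5 ± 48.7 CPM (log2 fold change 6.39 ± 0.45, adjusted p = 0.00671). Erfe, which encodes the erythroblast hormone erythroferrone (chromosome 1, 91366305 to 91374217), rose from 0.566 ± 0.114 to 9.20 ± 0.743 CPM (4.02 ± 0.41, adjusted p = 0.0166). Cish, a STAT5-induced inhibitor of cytokine signalling, rose by 2.43 ± 0.36 on the log2 scale, from 1.59 ± 0.229 to 8.64 ± 0.0572 CPM (adjusted p = 0.0359). The fatty acid binding protein gene Fabp5 rose by 2.40 ± 0.27 and the desaturase family gene Fads3 by 2.39 ± 0.34. The long non-coding RNA Redrum rose by 4.14 ± 0.65, Cttnbp2 by 3.55 ± 0.39 and the chloride channel accessory gene Clca3a1 by 3.29 ± 0.35. The remaining rises were Tfrc, Plod2, Ltbp1, Bnip3 and Ndrg1, described with their lists, and Slc30a10 (1.70), Lgals3bp (1.37) and Muc13 (1.17), named after their values were seen.

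The 8 largest falls were in Pax5, Cacna1i, Vpreb3, Blk, Chst3, Cd5l, Tnfrsf19 and Mertk. Pax5, the transcription factor of B cell commitment (chromosome 4, 44524748 to 44710694), had 372 counts over the wild-type libraries and 0 over the inducible HIF-1α libraries, at least 134-fold lower. Cacna1i, a calcium channel gene, had 193 counts against 0, at least 69.7-fold lower. Vpreb3, part of the B cell receptor assembly machinery, was 208-fold lower (interval 57.1 to 1720, 2 counts left), and the B lineage kinase gene Blk was 199-fold lower (67.7 to 967, 3 counts left). Cd5l, a macrophage-secreted protein, was 150-fold lower (41.2 to 1250, 2 counts left). Mertk, a receptor for apoptotic cells, was 128-fold lower (35.0 to 1060, 2 counts left). The sulfotransferase gene Chst3 fell from 46.1 ± 6.58 to 0.271 ± 0.384 CPM and Tnfrsf19 from 10.6 ± 2.57 to 0.0775 ± 0.11 CPM.

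All 157 called genes had no overlap between the genotypes, and the number called depended on the fit. With 2 libraries per group, chance alone separates 33.3% of genes, and 52.7% of the tested genes were separated. DESeq2 called 953 genes and edgeR's exact test 1121, and leaving out 1 library changed the edgeR quasi-likelihood count to 2 without wild-type replicate 1, 0 without wild-type replicate 2 (703 genes at an unadjusted p under 0.05, against 2373 with all 4 libraries), 4669 without inducible HIF-1α replicate 1 and 1666 without inducible HIF-1α replicate 2. Of the 47 called genes taken by the naming rule, 2 remained called without wild-type replicate 1 (Spib and Ms4a1), none without wild-type replicate 2, and all 47 without either inducible HIF-1α library. The calls of Redrum, Hba-a1, Hba-a2, Thbs1, Cxcr2, H2-Ab1, Ncr1, Ltbp1 and Btg2 were lost with total-count scaling, and all of these but H2-Ab1 also with the 10 most abundant genes left out. Of the 33 tested with at least 1 CPM in all 4 libraries, Hba-a1, Hba-a2, Thbs1, Cxcr2, Ncr1 and Ltbp1 were lost, and limma-voom did not call Redrum and Mertk.

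**Figure D1:**
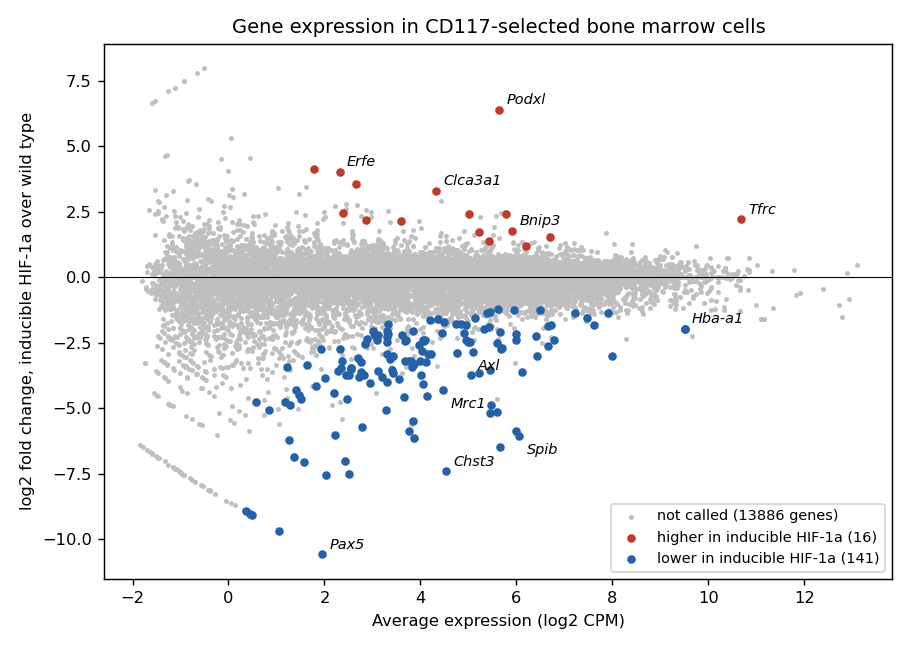
Each point is 1 of the 14043 tested genes, with its average expression in log2 CPM on the horizontal axis and its log2 fold change (inducible HIF-1α over wild type, 2 libraries each) on the vertical axis. Called genes (edgeR quasi-likelihood, adjusted p under 0.05) are coloured, and 118 of the 141 falls and 11 of the 16 rises lie beyond 2 on the log2 scale; fitted values of genes with no count in one group, such as Pax5, depend on the prior count and are not measured folds.

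B cell markers were the most reduced of the lists. All 21 tested members had negative fold changes, 15 fell past the threshold (all 21 when adjusted over the list alone) and the median log2 fold change was -4.76, a value that did not change with Pax5 set at its bound. Spib, a transcription factor of B cells and plasmacytoid dendritic cells (chromosome 7, 44525995 to 44532087), fell from 131.7 ± 1.88 to 1.98 ± 0.113 CPM (log2 fold change -6.05 ± 0.23, adjusted p = 0.000526). Ms4a1, encoding CD20, fell from 99.6 ± 11.2 to 1.11 ± 0.135 CPM. Bach2, a transcriptional repressor of lymphoid cells, fell by 2.85 on the log2 scale. The list was lower by camera (adjusted p = 2.76e-79 at the preset correlation, adjusted p = 0.433 with an estimated correlation).

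Markers of other mature blood cells were lower as well. Of 23 monocyte and macrophage markers 9 fell and none rose (18 fell when adjusted over the list alone), with a median log2 fold change of -1.49. Among them were the receptor tyrosine kinase gene Axl, which fell from 61.7 ± 0.33 to 4.57 ± 0.489 CPM, Mrc1, encoding the mannose receptor, which fell from 42.1 ± 2.74 to 2.15 ± 1.29 CPM, Adgre1, encoding F4/80, which fell from 25.1 ± 1.43 to 2.71 ± 0.766 CPM, and Mertk. Camera gave an adjusted p of 5e-27 (adjusted p = 0.433 with an estimated correlation). Of 21 mature neutrophil markers 3 fell and none rose (15 fell when adjusted over the list alone), with a median of -1.18. These were Retnlg, which fell from 153.8 ± 10.1 to 18.9 ± 9.96 CPM, the formyl peptide receptor gene Fpr1 (-2.48 ± 0.33) and the chemokine receptor gene Cxcr2 (-1.55 ± 0.24). The call of Cxcr2 was lost with some other scalings and filters (adjusted p = 0.0749 with total-count scaling, but 0.0476 with upper quartile scaling; range over alternatives 7.37e-20 to 0.726). Camera gave an adjusted p of 3.05e-16 (adjusted p = 0.511 with an estimated correlation). The 15 neutrophil primary granule genes, which mark earlier myeloid cells, all had negative fold changes with a median of -0.60, but none was called. Fcnb had the smallest p (-0.91 ± 0.30, adjusted p = 0.207). Camera called that list lower (adjusted p = 0.011, and adjusted p = 0.774 with an estimated correlation), and the call was lost without inducible HIF-1α replicate 2. Without inducible HIF-1α replicate 1, 21 monocyte and macrophage, 21 mature neutrophil and 15 primary granule genes fell and none rose. Without inducible HIF-1α replicate 2, 16 monocyte and macrophage genes fell and 1 rose, 14 mature neutrophil genes fell and no primary granule gene was called.

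Of 17 dendritic cell and MHC class II genes 4 fell and none rose, with a median of -1.67. These were Siglech (-2.56 ± 0.32), the transcription factor gene Irf4 (-4.89 ± 0.62), H2-Eb1 (-2.58 ± 0.33) and H2-Ab1 (-2.16 ± 0.30). Camera gave an adjusted p of 1.42e-09 (adjusted p = 0.433 with an estimated correlation). When adjusted over the list alone, 9 fell and 1, Zbtb46, was higher. Of 21 T and NK cell markers 2 fell, the T cell kinase gene Lck (-1.71 ± 0.22) and the NK receptor gene Ncr1 (-2.05 ± 0.30), and none rose; 11 fell when adjusted over the list alone. The median was -1.86 and the adjusted p by camera 2.33e-10 (adjusted p = 0.502 with an estimated correlation). Of 12 eosinophil markers 1 fell, the eosinophil ribonuclease gene Ear2 (-2.22 ± 0.31), and 6 fell when adjusted over the list alone. Camera gave an adjusted p of 1.4e-06 (adjusted p = 0.574 with an estimated correlation). None of 13 mast cell and basophil markers was called (2 lower when adjusted over the list alone). The basophil protease gene Prss34 had the smallest p (-1.13 ± 0.22, adjusted p = 0.0806). Camera did not call that list (adjusted p = 0.196), but called it lower with the filter of at least 1 CPM in all 4 libraries (adjusted p = 0.0493).

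Of 21 megakaryocyte and platelet markers 2 fell and none rose. Ppbp, encoding a platelet chemokine, fell from 12.1 ± 4.08 to 0.856 ± 0.0598 CPM, and Thbs1, encoding thrombospondin-1, fell from 184.2 ± 23.6 to 34.9 ± 17.8 CPM. The count was also 2 when adjusted over the list alone, the median was -0.69 and the camera adjusted p was 0.00158 (adjusted p = 0.539 with an estimated correlation). Of 17 stromal and endothelial markers 2 fell, Fn1, encoding fibronectin (-3.56 ± 0.29), and Cxcl12, a niche chemokine gene (-2.94 ± 0.30), and 4 fell when adjusted over the list alone. Camera gave an adjusted p of 1.4e-06 (adjusted p = 0.433 with an estimated correlation). In the fibrosis-linked list Thbs1 fell and Ltbp1, a latent TGF-β binding protein gene, rose from 4.38 ± 1.12 to 19.5 ± 5.23 CPM (adjusted p = 0.0426). When adjusted over the list alone, 3 of its 15 genes fell and 1 rose, and camera called the list lower (adjusted p = 0.0331, and adjusted p = 0.629 with an estimated correlation).

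Known HIF-1 targets were called higher as a list by camera at the preset correlation (adjusted p = 0.00206) but not with an estimated correlation (adjusted p = 0.433). Of 38 tested targets 3 rose and none fell, and 5 rose when adjusted over the list alone (with P4ha1 and Higd1a). Bnip3, a mitophagy receptor gene (chromosome 7, 138890836 to 138909506), rose from 27.2 ± 1.03 to 92.6 ± 2.68 CPM (log2 fold change 1.77 ± 0.19, adjusted p = 0.0169). Ndrg1, a hypoxia-induced gene, rose from 53.7 ± 0.514 to 155.7 ± 22.4 CPM, and Plod2, a collagen lysyl hydroxylase gene, from 2.60 ± 0.0196 to 11.8 ± 0.693 CPM. The median over the list was 0.21, with 24 positive and 14 negative values. The list call was lost without inducible HIF-1α replicate 1 (adjusted p = 0.169; 0.000135 to 0.0103 without each of the other libraries). Without Bnip3, Ndrg1 and Plod2, a test chosen after the result was seen, the other 35 targets had a median of 0.07 with 21 positive values, and the list did not pass (adjusted p = 0.111). By member, 14 targets rose and 10 fell without inducible HIF-1α replicate 1, 10 rose and none fell without inducible HIF-1α replicate 2, and none was called without either wild-type library. Of the fixed targets 11 are also in the glycolysis list. Vegfa (-0.22 ± 0.20) and Slc2a1 (-0.65 ± 0.31), HIF targets named after their values were seen, were not called. Among 12 HIF pathway components none was called, and Hif3a had the smallest p (2.27 ± 0.50, adjusted p = 0.1) and was the only one called when adjusted over the list alone. For this list the median was -0.09, the mean 0.09 and the camera direction up (adjusted p = 0.671).

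None of 22 glycolysis genes was called, also when adjusted over the list alone, the median was -0.11 and the list did not pass the test (adjusted p = 0.941). The smallest p belonged to Slc2a3, a glucose transporter gene (-0.96 ± 0.21, adjusted p = 0.101). Without inducible HIF-1α replicate 1, 5 glycolysis genes rose and 9 fell, and without inducible HIF-1α replicate 2, 3 rose and 2 fell (median 0.14). Both lists of mitochondrial respiration were called higher at the preset correlation only, with no single gene called. The tricarboxylic acid cycle list had a median of 0.21 (18 of 22 positive, Suclg2 0.68 ± 0.21), a camera adjusted p of 0.022 and an adjusted p of 0.774 with an estimated correlation. The oxidative phosphorylation list had a median of 0.15 (32 of 40 positive, Cox8a 0.69 ± 0.26), a camera adjusted p of 0.0223 and an adjusted p of 0.774 with an estimated correlation. Both calls were lost without inducible HIF-1α replicate 2, and that of oxidative phosphorylation also without wild-type replicate 2. Singly, 10 oxidative phosphorylation and 8 tricarboxylic acid cycle genes rose and none fell without inducible HIF-1α replicate 1. Without inducible HIF-1α replicate 2, 2 oxidative phosphorylation genes fell and none rose, and 1 tricarboxylic acid cycle gene rose and 1 fell. All 35 ribosomal protein genes had positive fold changes with a median of 0.43, none was called singly, and camera called the list higher (adjusted p = 7.57e-09, and adjusted p = 0.629 with an estimated correlation). Singly, 31 ribosomal protein genes rose without inducible HIF-1α replicate 1, and 10 rose and 1 fell without inducible HIF-1α replicate 2. Ribosomal protein genes share reads with many pseudogenes, so their single values are uncertain.

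**Figure D2:**
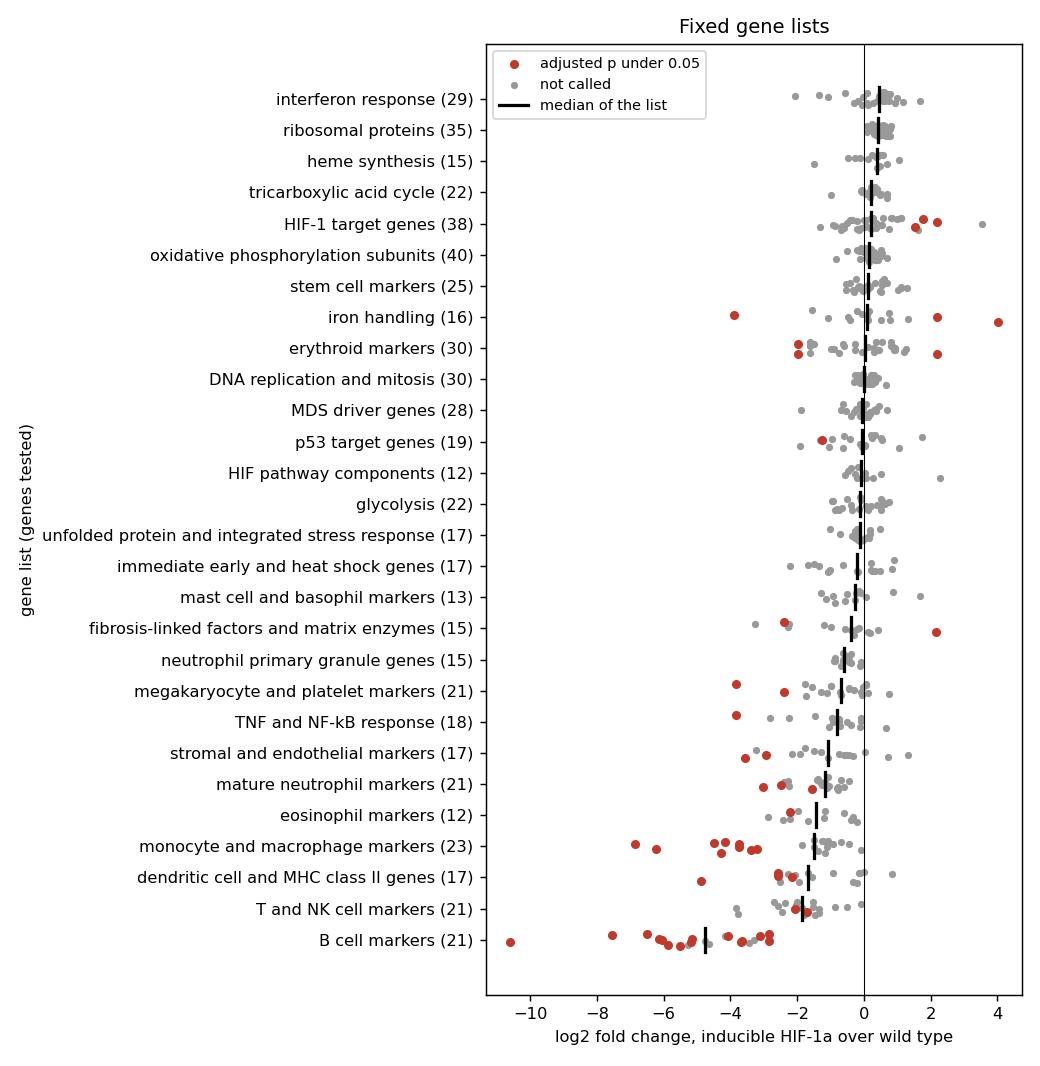
Each point is 1 gene of a list, placed by its log2 fold change (inducible HIF-1α over wild type); red points were called at an adjusted p under 0.05 and the black bar is the list's median. The B cell list lies apart at a median of -4.76, and in the HIF-1 target list 3 genes lie above 0 in red around a median of 0.21.

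Called erythroid and iron genes went both ways. Tfrc, the transferrin receptor gene (chromosome 16, 32608896 to 32632794), rose from 592.2 ± 99.5 to 2715 ± 641 CPM (log2 fold change 2.20 ± 0.26, adjusted p = 0.019). The α-globin genes Hba-a1 and Hba-a2, whose rows hold identical counts and are counted as 1, fell from 1161 ± 90.2 to 296.9 ± 125 CPM (-1.97 ± 0.31, adjusted p = 0.0434). Their log2 fold change was between -2.44 and -1.59 under every alternative run, but the call was lost with total-count scaling (adjusted p = 0.0641), DESeq2-type size factors, the stricter filter, the most abundant genes left out, or without either wild-type library (range over alternatives 1.37e-35 to 0.698). Of 27 distinct rows among the 30 tested erythroid markers these were the 2 called; adjusted over the list alone, Alas2 and the β-globin rows were lower too. With identical rows counted once, the erythroid median over 27 genes was 0.30. Over all 30 tested rows, which count the identical globin rows separately, the erythroid list had a median of 0.04 and a mean of -0.15. Its camera direction over those rows was down (adjusted p = 0.422). It was called in opposite directions by library: higher without inducible HIF-1α replicate 1 (adjusted p = 0.00824) and lower without inducible HIF-1α replicate 2 (adjusted p = 9.99e-12). Among 16 iron-handling genes Erfe and Tfrc rose and Hmox1, encoding the heme-degrading enzyme heme oxygenase 1, fell from 21.9 ± 0.0914 to 1.48 ± 1.03 CPM (-3.89 ± 0.50, adjusted p = 0.0235). When adjusted over the list alone 3 rose (with Tfr2) and 2 fell (with Trf), and the list did not pass the test (adjusted p = 0.134, and 0.0437, higher, without inducible HIF-1α replicate 1). None of 15 heme synthesis genes was called over all genes, and Alas2, the erythroid rate-limiting enzyme, had the smallest p (-1.50 ± 0.27, adjusted p = 0.0602). The list's median was 0.40, with 11 positive and 4 negative values, and camera did not call it (adjusted p = 0.316). The heme synthesis list was called higher without inducible HIF-1α replicate 1 (adjusted p = 0.000329).

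The libraries differed within the inducible HIF-1α group along the same lists. The mean log2 CPM of the erythroid list was 7.39 and 7.48 in the wild-type libraries, 6.88 in inducible HIF-1α replicate 1 and 7.87 in replicate 2. The mean of the mature neutrophil list was 8.71 and 8.72 in wild type, and 7.76 and 6.74 in inducible HIF-1α. The mean of the B cell list was 4.97 and 5.01 in wild type, and 0.916 and -0.734 in inducible HIF-1α.

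No stem cell marker was called among 25 (median 0.13, list adjusted p = 0.134); Tal1, a transcription factor of stem cells and erythroid cells, had the smallest p (1.01 ± 0.26, adjusted p = 0.132). The stem cell list was called higher without inducible HIF-1α replicate 2 (adjusted p = 0.000387; median 0.35, 4 rose and none fell), while without inducible HIF-1α replicate 1 its median was -0.43 and 4 rose and 6 fell. Kit, which encodes the antigen used for selection, had a log2 fold change of 0.53 ± 0.18 (adjusted p = 0.220) and was named after its value was seen. Of 28 MDS driver genes none was called (Setbp1 -1.87 ± 0.55, adjusted p = 0.176); the list's median was -0.05, its mean -0.09 and its camera direction up (adjusted p = 0.901). None of 30 replication and mitosis genes was called (median 0.02, Ccne2 0.65 ± 0.24, list adjusted p = 0.254, and 0.0152, higher, without inducible HIF-1α replicate 1). Of 19 p53 targets the antiproliferative gene Btg2 fell (-1.25 ± 0.19, adjusted p = 0.0375), and the list did not pass the test (adjusted p = 0.625). Adjusted over the list alone, 2 p53 targets fell (with Trp53inp1) and 1, Zmat3, rose, both named after their values were seen.

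Of 18 TNF and NF-kB response genes Cd83, an activation marker of dendritic and B cells, fell from 7.43 ± 0.581 to 0.513 ± 0.0682 CPM, and 8 fell when adjusted over the list alone. Camera gave an adjusted p of 0.000142 (adjusted p = 0.502 with an estimated correlation). None of 17 immediate early and heat shock genes was called (5 lower when adjusted over the list alone; Klf2 -2.20 ± 0.39, adjusted p = 0.059). Camera called that list lower (adjusted p = 0.0406, and adjusted p = 0.502 with an estimated correlation), and the call was lost without inducible HIF-1α replicate 1. None of 29 interferon response genes was called (Ifih1 0.99 ± 0.21, adjusted p = 0.0886; list adjusted p = 0.142), nor any of 17 unfolded protein and integrated stress response genes (Edem1 -0.73 ± 0.32, adjusted p = 0.309; list adjusted p = 0.762, and 0.0351, lower, without inducible HIF-1α replicate 1). The interferon list was called in opposite directions by library: lower without inducible HIF-1α replicate 1 (adjusted p = 0.0277) and higher without inducible HIF-1α replicate 2 (adjusted p = 4.57e-13).

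In the 14 lists with no gene called by edgeR's quasi-likelihood test, 56 genes in sum had an unadjusted p under 0.05, DESeq2 called 16, the exact test 19 and limma-voom 1, with genes in more than 1 list counted in each. Across the 28 lists camera called 4 higher and 12 lower at the preset correlation. With an estimated correlation none passed after adjustment (2 at an unadjusted p under 0.05), and by fry's directional test none passed (6 at an unadjusted p under 0.05). By fry's mixed test, which asks for change in either direction, 2 passed, the erythroid markers (adjusted p = 0.0232) and the B cell markers (adjusted p = 0.0437). The erythroid result counts the identical globin rows separately.

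The member counts of the remaining lists also depended on which inducible HIF-1α library was left out. Without replicate 1, 15 erythroid markers rose and 10 fell, 9 heme synthesis genes rose and 2 fell, and 7 iron-handling genes rose and 3 fell. Without replicate 2, 1 erythroid marker rose and 13 fell, 1 heme synthesis gene rose and 2 fell, and 3 iron-handling genes rose and 3 fell. Of the interferon genes 3 rose and 14 fell without replicate 1, and 15 rose and 1 fell without replicate 2. All 21 B cell markers fell in both cases. Without replicate 1 falls outnumbered rises among T and NK (17 and 0), dendritic (12 and 1), eosinophil (11 and 0), megakaryocyte (10 and 1), stromal (8 and 1), mast (5 and 1) and fibrosis-linked genes (5 and 2). Without replicate 2 the counts of falls and rises in these lists were 9 and 0, 9 and 0, 6 and 0, 5 and 0, 4 and 0, 3 and 0, and 3 and 1. Among TNF and NF-kB genes 10 fell and 1 rose without replicate 1, and 5 fell and none rose without replicate 2. Among immediate early genes 8 fell and 2 rose without replicate 1, and 5 fell and none rose without replicate 2. Among stress response genes 9 fell and 1 rose without replicate 1, and none fell and 1 rose without replicate 2. Of the MDS driver genes 7 fell and 3 rose without replicate 1, and none fell and 1 rose without replicate 2. Of the p53 targets 4 fell and 2 rose, and 3 fell and 2 rose. Of the replication genes 6 and 1 rose and none fell, and of the HIF pathway components 2 rose and 2 fell, and 1 rose and none fell.

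**Figure D3:**
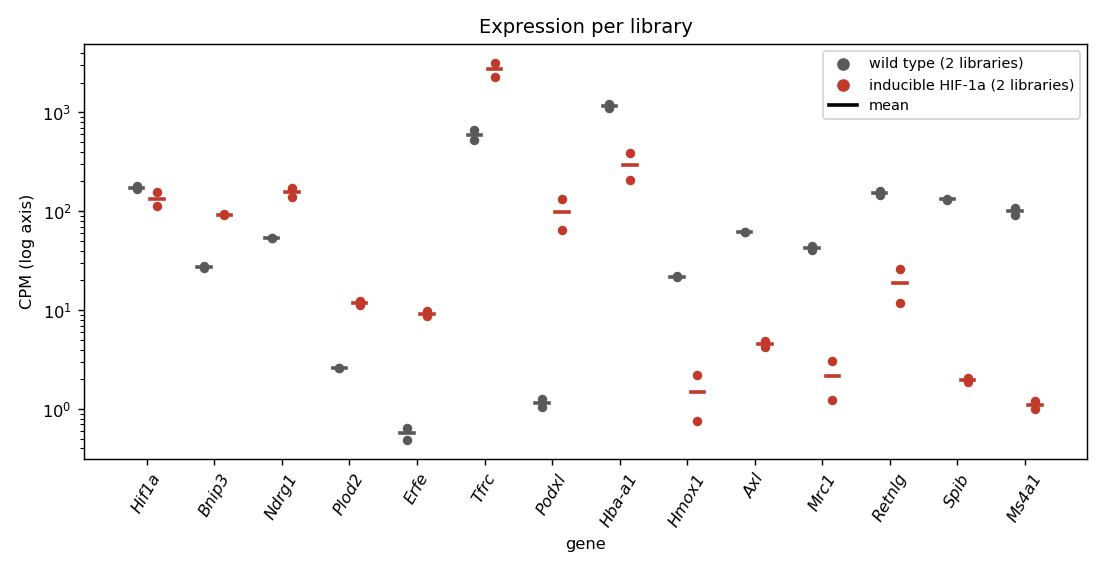
Expression of 14 named genes in CPM on a log axis; each point is 1 library, grey for wild type and red for inducible HIF-1α, and the bar is the mean of 2 libraries. The genotypes overlap for none of the genes shown, and Hif1a, the 1 gene shown that was not called, lies at 155.15 and 112.67 CPM in inducible HIF-1α against 178.99 and 168.38 CPM in wild type.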

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

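The number of called genes, 157 with all 4 libraries, depended on the tool, filter and scaling. DESeq2 called 953 genes (156 of the 157 among them), edgeR's exact test 1121, the fit with no filter on low counts 747, a filter of at least 1 CPM in all 4 libraries 78 and total-count scaling 97. In the simulated data DESeq2 called 133 of 200 changed genes with 19 false calls, and the exact test 132 with 31. Limma-voom called 113 with 7 false calls. The quasi-likelihood test made 5 false calls there, 4.07% of its calls. The larger counts of DESeq2 and the exact test may thus hold more false calls. Thresholds of 0.01 and 0.1 gave 10 and 409. Leaving out each library gave 0 to 4669: the fits without a wild-type library take their spread from the inducible HIF-1α pair, and those without an inducible HIF-1α library from the closer wild-type pair, with the lone library assumed to vary like the other group. No called gene reversed, but genes whose groups do not overlap could hardly do so, which says nothing about stability. DESeq2-type and upper quartile scaling, the most abundant genes left out, identical rows counted as 1 (chosen after seeing the data) and limma-voom stayed within 1.5 times the main count. The wild-type and inducible HIF-1α libraries share replicate numbers 1 and 2, but nothing shows that these pair them: the difference between replicates correlated by 0.077 across genes between the genotypes. With a replicate block 381 genes were called, including all 157.

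Of the 47 called genes taken by the naming rule, all 47 held with DESeq2, upper quartile scaling and the replicate block. Because DESeq2 made more false calls in the simulated data than the quasi-likelihood test, holding with it is a weaker check. With size factors of the DESeq2 type 44 held, with total-count scaling 38, with the 10 most abundant genes left out 39, with limma-voom 45 and with at least 1 CPM in all 4 libraries 27 of the 33 tested. Without wild-type replicate 1 only 2 held and without wild-type replicate 2 none. The change in Hif1a ranged from -0.63 to -0.13 when 1 library was left out, and it passed the threshold only without inducible HIF-1α replicate 1. The count of 16 called lists ranged from 15 to 20 when 1 library was left out, with the erythroid and interferon lists called in opposite directions, and was 0 with an estimated correlation and 0 by fry's directional test, while 2 passed fry's mixed test; the cause was not tested. In simulated data the estimated correlation missed a shifted list (adjusted p = 0.0625), but fry called it (adjusted p = 0.0141). Those genes were drawn independently and the adjustment covered only a shifted and an unshifted list. In the real lists the estimated correlation reached 0.924 (primary granule genes), so the simulation does not show which list test is right here. A higher correlation does not account for every lost call. For the HIF-1 target list the estimate was 0.00755, below the preset 0.01. Its unadjusted camera p was still 0.000808 at the preset and 0.0741 with the estimate. The estimates for the stromal (-0.0249) and immediate early (-0.0172) lists were also below the preset. The effect of depth was not tested. For genes with 0 to 3 counts in the inducible HIF-1α libraries depth sets only a bound or a wide interval.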

Other observations

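The tests in this part were chosen after the results were seen. Macrophages that clear red cells and recycle heme iron express a group of genes, 8 of them in the fixed monocyte and macrophage list and Hmox1 and Slc40a1 in the iron list. Of 14 such genes 9 fell and none rose, with a median log2 fold change of -3.75 (camera adjusted p = 1.81e-30 over the 7 lists chosen this way, and adjusted p = 0.0723 with an estimated correlation, which does not pass); 6 of the 9 are in the fixed macrophage list. Siglec1, encoding the sialoadhesin of marrow macrophages, fell from 8.62 and 8.59 CPM to 0.39 and 0.41 CPM. C1qa fell from 4.22 and 5.03 CPM to 0.12 and 0 CPM. Slc40a1, encoding the iron exporter ferroportin, was not called (-0.20 ± 0.18). Neither were Spic (-2.31 ± 1.26), Cd163 (-1.39 ± 0.32), Vcam1 (-1.49 ± 0.36) and Timd4 (-2.75 ± 0.68), so the calls do not cover the whole group.

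Of 7 early B lineage genes, all of them members of the fixed B cell list, 2 fell, Il7r and Rag2. The median was -4.15 (camera adjusted p = 1.63e-14, and adjusted p = 0.179 with an estimated correlation). Igll1, Vpreb1 and Vpreb2 did not pass. Rag1 went from 92.3 and 93.0 CPM to 7.09 and 0.37 CPM and Dntt from 103.2 and 123.2 CPM to 18.1 and 5.13 CPM, neither past the threshold over all genes.

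The first pattern is the near loss of B lineage transcripts. A loss of later B stages alone would leave the early B lineage genes largely unchanged, but their median was -4.15 (SD 0.81 over 7 genes). These values argue against it, as far as the later stages do not themselves express these 7 genes, which was not measured. They are not an independent test, because all 7 genes belong to the fixed B cell list, whose falls had been seen. Fewer CD117-negative cells of all types alike would lower B cell and T and NK markers together, but their medians differed by -2.90 (SD 1.83 and 0.90), and by -2.77 for the 7 T and NK genes in no other list with at least 5 CPM in wild type. That argues against an equal loss of all types as the whole cause, as far as CD117-positive cells do not express those 7 genes, which was not measured. The B cell median differed from that of the heme-recycling macrophage genes, chosen after their falls were seen, by -1.01, within the SDs. The fixed monocyte and macrophage list fell less (median -1.49). The mean log2 CPM of the B cell list minus that of this fixed list was 0 and -0.02 in wild type. In inducible HIF-1α it was -2.22 and -2.85. Transcripts of that fixed list thus fell less than those of the B cell list. This argues against an equal loss of the cells only as far as CD117-positive cells do not express the fixed list's genes. Their expression there was not measured. A loss shared by B cells and the macrophages of the chosen genes stays open, and fewer B lineage cells in the marrow was not tested.

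The second pattern is the rise of Tfrc beside the fall of α-globin. More early erythroid RNA would raise Gata1, Klf1, Epor and the like by about as much as Tfrc (2.20 ± 0.26). The median of 10 such genes was 0.89, and the highest, Rhag, was at 1.27 ± 0.44. Their SD of 0.19 is a spread across genes in the same libraries, not an error of the genotype difference. More RNA of these early erythroid genes is thus unlikely to be the whole cause of the Tfrc rise. In inducible HIF-1α replicate 1 these genes stood at 1.23 times their wild-type mean and Tfrc at 3.82 times; in replicate 2 they stood at 2.5 and 5.35 times. Less late erythroid RNA stays open for α-globin (-1.97 ± 0.31): the median of 14 late rows was -0.67 (SD 0.64), but Hbb-bs (-1.62 ± 0.38), Hbb-bt (-1.61 ± 0.39) and Alas2 (-1.50 ± 0.27) lay within the summed SEs. Erfe and Cish are known to respond to erythropoietin through STAT5, a possible explanation that stays open: the other 7 genes of such a list went both ways, with 4 positive. Camera (limma) over those genes gave an adjusted p = 0.833, which decides nothing.

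The third pattern is the rise of Bnip3, Ndrg1 and Plod2. More early erythroid RNA would raise the early erythroid genes about as much as Ndrg1 (1.54 ± 0.19), the smallest of these rises. Their median of 0.89 was lower. The highest of them, Rhag (1.27 ± 0.44) and Car1 (1.20 ± 0.47), lay within the summed SEs of Ndrg1 and of Bnip3 (1.77 ± 0.19). The median early erythroid gene stood at 1.23 times its wild-type mean in inducible HIF-1α replicate 1 and at 2.5 times in replicate 2. In replicate 1, where Ndrg1 stood at 2.6 and Bnip3 at 3.34 times, that argues against more early erythroid RNA as the whole cause. In replicate 2 this cause stays open for Ndrg1 and Bnip3, with Rhag at 546.05 CPM against 165.48 and 142.76 CPM in wild type. A larger share of stem cell RNA after the loss of mature cells would raise the stem cell markers as much, but their median was 0.13 (SD 0.54 over genes). That median was 0.35 without inducible HIF-1α replicate 2 and -0.43 without replicate 1. The comparison covers stem cell markers only, so a larger share of RNA of other progenitors was not tested and stays open. In the inducible HIF-1α libraries Bnip3 stood at 3.34 and 3.48 times, Ndrg1 at 2.6 and 3.19 times and Plod2 at 4.73 and 4.35 times the wild-type mean. A response of these genes to the induced HIF-1α is a hypothesis that may account for the rise. The HIF-1 target list was fixed before the data were examined, but these 3 genes were picked from it by their calls. The comparisons above were chosen afterwards on the same data, and strain differences between the genotypes were not tested.

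The interferon list split the inducible HIF-1α libraries: of 29 genes, 24 were above both wild-type libraries in replicate 1 and 19 were below both in replicate 2. In CPM of the unscaled total count, Xist was detected at 9.15 and 8.42 CPM in the wild-type libraries and 2.41 and 1.40 CPM in the inducible HIF-1α libraries, while the Y-linked gene Ddx3y was at 178.8 to 221.7 CPM in all 4. The deposited rows Gm4070 and Gvin1 hold identical counts of 12307, 9519, 33099 and 6726 in the 4 libraries.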
